A study of Rattus norvegicus with 5 samples.

How the data were processed

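The data are 1-colour miRNA array measurements of RNA from rat hearts, labelled with Hy3 per the labels: 1 sham sample and 4 TAC samples, each from the hearts of 5 rats and hybridized to 1 array. The raw table gives, per the file headers, the foreground intensity of each of 12312 spots and the intensity after the authors' subtraction of background, neither of them normalized between arrays. The scanner and image software are not given in the sources used here. The authors' processed table holds, for each probe, the ratio of its median background-subtracted signal to 1 constant per array. This was found from the values: the constants were 1036.5 for sham and 733, 1036.5, 991 and 1074.5 for TAC days 5, 10, 15 and 20, every value met them within a relative deviation of 6.89e-07, and probes at or below 0 were blank. The rule behind the constants is not given in the sources used here. The ratios are on a linear scale and not centred per gene, and their medians per array were 0.192, 0.360, 0.243, 0.284 and 0.182.

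The header of the raw column used for sham carries day 15, while the label of the sham sample says 5 days after surgery. The column was assigned from the processed table, whose sham column is an exact multiple of it. Which day is right was not settled, so the time match between the sham and TAC day 5 arrays rests on the label.

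Background was taken as foreground minus the background-subtracted value of the same spot. Foregrounds were corrected by normexp with an offset of 50, the arrays were quantile normalized over the spots of the 678 rat miRNA probes, and the 4 spots of a probe were averaged on the log2 scale (limma 3.58.1 in R 4.3.3). Offset and quantile scaling shrink the ratios of dim probes. A miRNA counted as detected on an array when its mean background-subtracted signal was above the median plus 3 MAD of the array's empty and negative-control spots. The MAD was scaled to match an SD, which the plan did not specify. The floors were 30.6 units on sham and 72.1, 46.4, 46.4 and 28.1 on TAC days 5 to 20, and the median background was 104, 206, 152, 144 and 101 units. MiRNAs detected on all arrays had a median signal of 1055.2, 948.5, 1195.2, 1019 and 1100.5 units. On sham, TAC day 10, day 15 and day 20, 4, 6, 4 and 2 rat spots were at the ceiling of 65535 units, and on TAC day 5 there were 0. They belonged to miR-22, miR-23b, miR-126 and miR-208, whose ratios the ceiling limits.

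Probes for controls and 1901 probes without a name were left out of the comparisons and are described only in the closing section and where spike-ins are named. Values of control and unnamed probes are median-scaled log2 ratios. Those of spike-ins are over the 47 of 51 spike-in probes above the floor on sham. The authors' blanks, 1759, 1829, 1794, 1822 and 1585 probes, all had a median signal at or below 0. Where a miRNA was above the floor on 1 of the arrays compared, only a bound against the floor was computed. Bounds were not recomputed under the alternative choices below.

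Designs, lists and rules were fixed before the data were examined. With 1 array per group, each comparison of a TAC array with sham is a count of miRNAs at 2-fold or more among those detected on both arrays, with no test across samples. No paired analysis was possible because each group has 1 array. The SE over spots is technical and says nothing about the spread between hearts. It also takes spots as independent, although the block sets of a slide differed. The median spot SD on the log2 scale was 0.12 on sham and 0.24, 0.63, 0.43 and 0.24 on the TAC arrays. The only planned test across arrays was limma with eBayes (trend) of 1 array against the other 4, with sham as the lone array and, for comparison, with each TAC array in its place. It had 3 residual degrees of freedom and Benjamini-Hochberg adjustment over 273 miRNAs detected on at least 1 array. Its p-values measure only these arrays and assume that the lone array varies like the others. The median ratio of each of 16 lists was ranked among 10000 random lists of the same size, matched on mean log2 intensity, where 3 or more members were detected. The percentile describes these arrays and is not a test across animals.

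Named miRNAs were chosen by rule. For each comparison the rule took up to 5 highest and 5 lowest at 2-fold or more whose spots on the 2 arrays did not overlap, which chance gives for 2.86% of probes with 4 spots on each array. It also took the 10 largest in each direction among miRNAs on the same side of sham at all 4 times, up to 4 members of each list with the largest absolute medians, 10 miRNAs of cardiac interest fixed by name (both strands of miR-199a were read), and the 5 with the largest range within TAC. Other members of a list are named only within the description of that list. The lists covered muscle-enriched miRNAs and miRNAs known from earlier work to rise or to fall in pressure-overloaded hearts. They also covered the miR-29 and miR-30, miR-15/16 and let-7 families, miR-17/92 and its paralogous clusters, and the Dlk1-Dio3 cluster. Another was the rodent repeat cluster of miR-297, miR-466 and miR-467 (with miR-290 to miR-295 of a separate cluster). The rest held endothelial, smooth muscle, fibroblast, erythroid and leukocyte miRNAs, inflammation- and hypoxia-responsive miRNAs, and markers of other tissues. Several miRNAs stand in more than 1 list, and heart cells also express many of the cell type markers.

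Each result was recomputed, where the choice applied, with plain background subtraction, no background correction, median scaling, cyclic loess, the authors' processed values, a floor 3 times higher, no floor, the median of spots, a 1.5-fold threshold, limma without trend, and each TAC array left out. Quantile scaling over all probes other than controls, spike-in scaling, either block set alone, and days 15 and 20 only were added after seeing the data. Spike-in scaling used the 30 spike-in probes above the floor on all arrays and was not run for named miRNAs. A scaling shift is the change in the median ratio of all miRNAs detected on both arrays. In the order of TAC days 5, 10, 15 and 20 the shifts were -0.16, -0.20, -0.05 and 0.04 with median scaling, -0.10, -0.16, -0.13 and -0.10 with cyclic loess, -0.18, 0.03, -0.03 and 0.03 in the authors' values, -0.73, -0.32, -0.22 and -0.15 with quantile scaling over all probes, and -0.48, -0.23, -0.33 and 0.34 with plain subtraction.

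The steps were tested on simulated data built from the sham array, with 80 miRNAs set to known 2-fold or 4-fold differences. The same differences were set on all 4 TAC arrays. Every simulated array had the sham background, an added spot SD of 0.2 and no added difference between block sets. The real arrays had a median spot SD of up to 0.63 and a background of up to 206 units, against 104 on sham. The recovery below may therefore not hold for them. With an array SD of 0.3 on the log2 scale, 13 of 35 detected 2-fold and 30 of 37 detected 4-fold differences reached the 2-fold threshold, and 2 unchanged miRNAs did. Limma then called 30 of 40 and 39 of 40, and 1 unchanged miRNA. With an array SD of 0.6, 13 of 37 and 26 of 37 reached 2-fold along with 20 unchanged miRNAs, and limma called 2 of 40 and 21 of 40, and 2 unchanged miRNAs.

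Gene positions for the test of neighbouring genes came from a RefSeq gene table, in which 270 of the 273 miRNAs were found and 249 had exactly 1 gene. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.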

Results

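MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured in rat hearts after transverse aortic constriction (TAC), surgery that narrows the aorta and loads the left ventricle with pressure, and after sham surgery. There were 5 arrays, each hybridized with Hy3-labelled RNA from the hearts of 5 rats: 1 sham array labelled as 5 days after surgery and 4 TAC arrays, from 5, 10, 15 and 20 days after surgery. With 1 array per group, no spread between hearts can be given for any value, and the SE printed with a log2 ratio covers only the 4 spots per probe on the arrays compared. The number of arrays limits the precision of every comparison. Of 678 rat miRNA probes, 236 were above the detection floor on the sham array, 162 on TAC day 5, 213 on day 10, 207 on day 15 and 257 on day 20. The floors were 30.6, 72.1, 46.4, 46.4 and 28.1 units of background-subtracted signal, and 143 miRNAs were above the floor on all 5 arrays.

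Each TAC array was set against the sham array, to ask which cardiac miRNAs differed from sham at that time after constriction. The sham array was matched in time, by its label, with the day 5 array alone, although the header of its raw data column carries day 15. Among miRNAs above the floor on both arrays, 103 of 152 (67.8%) differed 2-fold or more on day 5, 58 of 197 (29.4%) on day 10, 15 of 201 (7.5%) on day 15 and 4 of 231 (1.7%) on day 20. Synthetic spike-in controls read lower on the TAC arrays, in the same order: relative to the miRNAs, the median over 47 spike-in probes was -2.10 on the log2 scale on day 5, -1.78 on day 10, -0.57 on day 15 and -0.41 on day 20. Blocks 19 to 36 of the slide read above blocks 1 to 18 by a median log2 difference of 0.998 on day 10 and 0.66 on day 15, against 0.15 on sham. Ratios of miRNAs below are relative to quantile-scaled rat miRNAs. Scaling to the spike-ins would raise the median ratio by 2.02 on day 5, 1.89 on day 10, 0.80 on day 15 and 0.44 on day 20.

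**Figure D1:**
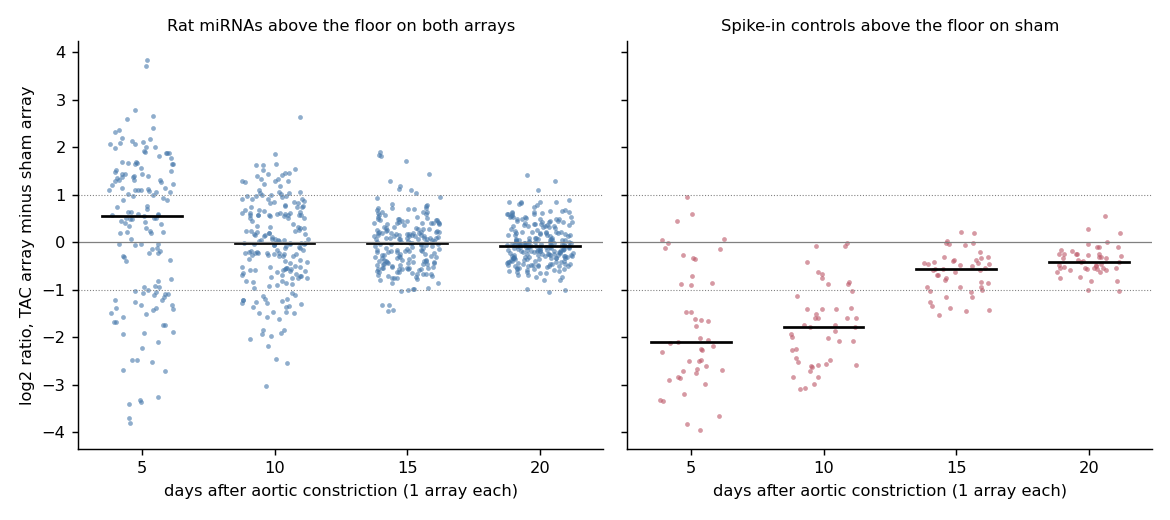
Log2 ratios of each TAC array to the sham array, 1 point per rat miRNA above the floor on both arrays (left) or per spike-in control above the floor on sham (right), with black lines at the medians and dotted lines at 2-fold. The miRNA ratios spread most on day 5 (SD 1.58) and least on day 20 (SD 0.43), and the spike-in medians lie at -2.10, -1.78, -0.57 and -0.41.

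On the TAC day 5 array, miR-21, which is known to be abundant in cardiac fibroblasts and to increase in hypertrophic hearts, read 3.25-fold higher than on sham (log2 ratio 1.70 ± 0.11, SE over spots). With quantile scaling over all probes the log2 ratio of rno-miR-21, TAC day 5, was 0.97, under 2-fold. The endothelial miRNA miR-126 read 13.9-fold lower (-3.80 ± 0.21), the smooth muscle miRNA miR-143 12.9-fold lower (-3.69 ± 1.04) and the erythroid miRNA miR-451 9.59-fold lower (-3.26 ± 0.06). The other smooth muscle miRNA, miR-145, read -0.125 ± 0.16. Over the alternatives the day 5 ratio of miR-143 ranged from -5.19 to -2.28. Among miRNAs above the floor on both arrays, 63 read 2-fold or more higher and 40 lower. Another 10 were above the floor on TAC day 5 alone, 6 of them at least 2-fold higher, and 84 on sham alone, 20 of them at least 2-fold lower. The farthest above sham were let-7c (3.84 ± 0.52), miR-331* (3.72 ± 0.49), miR-3571 (2.80 ± 0.32), miR-138-2* (2.66) and miR-207 (2.60). The farthest below sham, beside miR-126 and miR-143, were miR-125b-5p (-3.41 ± 1.02), miR-378 (-3.37) and miR-130a (-3.31 ± 0.34).

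Muscle-enriched miRNAs did not move together on day 5: of 7 above the floor on both arrays, 3 read 2-fold or more higher and 1 lower. Their median of 0.50 turned to -0.33 with median scaling. MiR-206 read 1.89 ± 0.26, miR-133a 1.32 ± 0.11 and miR-1 1.10 ± 0.10, whereas miR-499, encoded in a myosin heavy chain gene, read -2.48 ± 1.12. MiR-1 and miR-133a, which restrain cardiomyocyte growth, owe these ratios to the scaling: with arrays scaled by their median, the log2 ratio of rno-miR-1, TAC day 5, was -0.19 and the log2 ratio of rno-miR-133a, TAC day 5, was 0.06. The background-subtracted signal of miR-1 was 15260 units on sham and 11366 on day 5, while that of miR-21 was 2493 units on sham and 4273 on day 5. MiR-208, encoded in the alpha myosin heavy chain gene, read 0.30 ± 0.11, and miR-208b-3p, encoded in the beta myosin heavy chain gene, read -0.21 ± 0.09.

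Lists of miRNAs that earlier work found to rise or fall in pressure-overloaded hearts did not move in those directions as groups on day 5. Of 13 measured members of the list known to rise, 2 read 2-fold or more higher, miR-21 among them, and 6 lower, including miR-195 (-2.70 ± 0.08) and miR-199a-3p (-1.02 ± 0.24). Of 14 measured members of the list known to fall, 4 read higher and 5 lower. MiR-214, on the list known to rise, read -0.02. In the miR-29 and miR-30 families, whose members repress collagen and other matrix genes, 2 of 9 read 2-fold or more higher and 4 lower. MiR-30d read 1.24 ± 0.13, miR-30c -1.73 ± 0.21, miR-29a -1.69 ± 1.74 and miR-29b 1.14 ± 0.19. With median scaling the log2 ratio of rno-miR-29b, TAC day 5, was -0.12 and that of miR-30d 0.35, and in blocks 19 to 36 the log2 ratio of rno-miR-29a, TAC day 5, was 0.63.

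Members of the let-7 family, which share a seed sequence and differ by few bases, read in opposite directions on day 5: 5 of 8 were 2-fold or more higher and 2 lower, among them let-7c (3.84 ± 0.52), let-7e (1.11 ± 0.22), let-7b (-1.22 ± 0.27) and let-7i (-1.38 ± 0.21). With median scaling let-7e read 0.28, under 2-fold, and the median of the let-7 list went from 1.29 to 0.39. All 3 measured members of the miR-15/16 family, which restrains the cell cycle, read lower, with miR-16 at -2.52 ± 0.10. Of the 3 erythroid and blood cell miRNAs measured, each read 2-fold or more lower (miR-144 at -2.11 ± 0.18). So did 3 of 5 leukocyte miRNAs (miR-181a at -1.74 ± 0.29) and both endothelial miRNAs measured, which are the 2 strands of miR-126. The strand miR-126* read -1.08 ± 0.08, and -0.92, under 2-fold, in an alternative. For the miR-15/16 and the erythroid lists the median ratio was -2.52, and it was -0.80 with spike-in scaling. The median of the leukocyte list, -1.15, turned to 0.92 with spike-in scaling, and that of the list known to rise turned from -0.38 to 1.06. For miRNAs above the floor on sham and not on TAC day 5, only bounds can be given. They hold for the quantile scaling over rat miRNAs and were not recomputed under the alternatives. MiR-15b was at least 4.45-fold lower, miR-146a at least 4.50-fold lower and miR-34a at least 4.06-fold lower. The largest bounds, named after their values were seen, were miR-191 at least 7.47-fold lower and miR-653*, above the floor on TAC day 5 and not on sham, at least 8.76-fold higher.

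The split of 63 higher and 40 lower on day 5 depends on the scaling. It was 54 and 43 with median scaling, 49 and 49 with plain background subtraction, 24 and 47 with quantile scaling over all probes other than controls, and 114 and 7 with spike-in scaling, where 22 of the 103 ratios changed sign through the shift common to all miRNAs.

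On the TAC day 10 array, miR-21 again read higher than on sham (1.03 ± 0.37), while miR-208 (-1.11 ± 0.30) and miR-499 (-1.96 ± 0.77), both encoded in myosin genes, read lower. MiR-144 (-2.54 ± 0.38) and miR-451 (-1.83 ± 0.98), which are transcribed together in erythroid cells, read lower as well. In all, 27 miRNAs read 2-fold or more higher and 31 lower. The farthest above sham were let-7c (2.64 ± 0.66), miR-34b* (1.87), miR-347 (1.64), miR-3571 (1.63 ± 0.14) and miR-9* (1.62). The farthest below sham were miR-125b-5p (-3.02 ± 1.13), miR-144, miR-130a (-2.46 ± 0.71), miR-1949 (-2.19 ± 0.47) and miR-190 (-2.04 ± 0.48).

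Of 7 muscle-enriched miRNAs on day 10, 1 read 2-fold or more higher (miR-206, 1.04 ± 0.18) and 2 lower (miR-208 and miR-499), with miR-133a at 0.92 ± 0.15 and miR-1 at 0.30 ± 0.15. Among 5 erythroid and blood cell miRNAs 2 read 2-fold or more lower, and the list median of -0.90 lay at percentile 2.2 of random lists matched for brightness. With spike-in scaling the erythroid median was 0.59, still low among random lists at percentile 0.8. The list left that tail in blocks 19 to 36 alone (median -0.18, percentile 20.7), in the authors' processed values (percentile 13.6) and with plain background subtraction (percentile 7.3). It also lay outside the lowest 2.5 percent with the median of spots (percentile 4.1), no floor (3.1), no background correction (3.0) and quantile scaling over all probes (2.8). In the list known to rise 1 of 15 read 2-fold or more higher and 4 lower, and in the list known to fall 1 of 16 read higher and 2 lower. Of 5 inflammation- and hypoxia-responsive miRNAs 1 read higher and 3 lower, with miR-146b, a target of the inflammatory regulator NF-kappa-B, at -1.13 ± 0.39 and miR-210, which responds to low oxygen, at -1.25 ± 0.56. The inflammation and hypoxia list had a median of -1.13, which turned to 0.72 with spike-in scaling. In the let-7 family 2 of 8 read 2-fold or more higher (let-7c and let-7e) and 1 lower (let-7b, -1.36 ± 0.45). Of 3 endothelial miRNAs 1 read 2-fold or more lower, miR-126 at -1.06 ± 0.87. On day 10, 2 of its 4 spots were at the ceiling of the scale, so its ratio may lie within 2-fold, and in blocks 19 to 36 the log2 ratio of rno-miR-126, TAC day 10, was 0.11.

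Position on the slide and scaling both limit the day 10 values. In blocks 1 to 18 alone miR-208, with 1 of its sham spots at the ceiling of the scale, read -0.096 and miR-9* 0.67, and in blocks 19 to 36 alone miR-206 read 0.34 and miR-451 -0.55. Of the 58 miRNAs at 2-fold, 11 were 2-fold higher and 15 lower in both block sets taken separately. With spike-in scaling 158 miRNAs read higher and 1 lower, 21 of the 58 ratios changed sign through the common shift, and plain background subtraction gave 27 and 64.

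On the TAC day 15 array, let-7c (1.91 ± 0.52), miR-3571 (1.81 ± 0.11) and miR-675, which is processed from the imprinted H19 RNA (1.72 ± 0.10), read farthest above sham, with let-7c-1* (1.84) and miR-181a-2* (1.43). MiR-21 (0.08 ± 0.12), miR-1 (-0.03 ± 0.14) and miR-126 (-0.18) read close to sham. In all, 10 miRNAs read 2-fold or more higher and 5 lower. Of those 5, all 4 spots lay below all 4 sham spots only for miR-338 (-1.43 ± 0.37). The other 4 were miR-125b-5p (-1.45 ± 1.07), miR-125a-5p (-1.33), miR-190 (-1.32) and miR-378 (-1.01 ± 0.70). Each of these 4 read within 2-fold in 1 of the block sets, miR-378 at -0.27 in blocks 1 to 18 and, in blocks 19 to 36, miR-125b-5p at -0.72, miR-125a-5p at -0.42 and miR-190 at -0.40.

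No list had more than 1 member at 2-fold on day 15. MiR-150, enriched in mature lymphocytes, was 1 of 8 leukocyte miRNAs at 2-fold (1.03 ± 0.43) and also the 1 of 16 in the list known to fall that read 2-fold higher, against a fall in earlier work. All 4 measured members of the list for the imprinted Dlk1-Dio3 region read above sham (median 0.58), with miR-323 at 0.93 ± 0.50. The list leaves out some neighbouring genes. Of these, miR-136 was at least 1.47-fold lower, while miR-1193-3p read 0.30 and miR-667 0.495. The muscle-enriched list had a median of 0.16, which turned to -0.07 with quantile scaling over all probes, with miR-133a at 0.50 ± 0.06 and miR-208b-3p at 0.60 ± 0.24. In both block sets taken separately, 5 miRNAs were 2-fold higher and 1 lower. The 15 miRNAs became 65 with plain background subtraction (10 higher, 55 lower), 34 in the authors' processed values (20 higher, 14 lower) and 70 with spike-in scaling (69 higher, 1 lower).

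On the TAC day 20 array, 5 of 8 leukocyte miRNAs read above sham, though none by 2-fold. They were miR-150 (0.79 ± 0.34), miR-146a (0.74 ± 0.15), the myeloid miR-223 (0.64 ± 0.27), and both strands of the blood-cell gene miR-142, miR-142-5p (0.59 ± 0.19) and miR-142-3p (0.55 ± 0.13). MiR-181a (-0.62 ± 0.50), miR-181b (-0.61 ± 0.11) and miR-146b (-0.27) read below sham. The leukocyte list median of 0.57 lay at percentile 99.9 of matched random lists, and it was 0.88 with spike-in scaling. In blocks 1 to 18 alone the leukocyte median was 0.48, at percentile 94.9. Only 4 of 231 miRNAs differed 2-fold or more: miR-193 (1.43 ± 0.18), miR-450a* (1.29 ± 0.11) and miR-331* (1.11 ± 0.09) read higher, and miR-352 (-1.05 ± 0.21) read lower. Over the alternatives miR-450a* came as near sham as 0.90 and miR-352 as -0.74, both under 2-fold.

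Fibroblast and mesenchymal miRNAs read lower on day 20 at the median (-0.57, percentile 0.2), with 5 of 7 below sham, among them miR-31 (-0.97 ± 0.28), miR-152 (-0.80 ± 0.66) and both strands of miR-199a (miR-199a-5p at -0.59 ± 0.19 and miR-199a-3p at -0.57 ± 0.63). MiR-21 and miR-10a-5p, which are on the same list, read 0.44 ± 0.05 and 0.66 ± 0.72. MiR-10b, also on it, was above the floor on TAC day 20 and not on sham, at least 1.9-fold higher. In blocks 19 to 36 alone the median of fibroblast and mesenchymal miRNAs, TAC day 20, was -0.03, at percentile 61.4. With no floor it was -0.21, at percentile 7.5. Of 5 measured members of the Dlk1-Dio3 list 4 read above sham (median 0.50, percentile 99.2), with miR-300-5p at 0.86 ± 0.11 and miR-323 at 0.65 ± 0.14. The list leaves out some genes within 10 kb of its members. Of these, named after their values were seen, miR-136 (-0.64) and miR-665 (-0.13) read below sham. MiR-1193-3p (0.37) and miR-667 (0.15) read above it. The Dlk1-Dio3 median lay at percentile 83.9 in the authors' processed values, 89.3 with plain background subtraction and 97.0 with quantile scaling over all probes. Over all 40 probes of the list, most of them below the floor, it was 0.0019. The muscle-enriched median was -0.10, with miR-133a at 0.35 ± 0.12, miR-208 at -0.34 ± 0.26 and miR-208b-3p at 0.63 ± 0.26. The muscle-enriched median turned to 0.18 with spike-in scaling. The count of 4 became 51 with plain background subtraction (47 higher, 4 lower), 36 in the authors' processed values (30 higher, 6 lower) and 33 with spike-in scaling (33 higher, 0 lower).

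**Figure D2:**
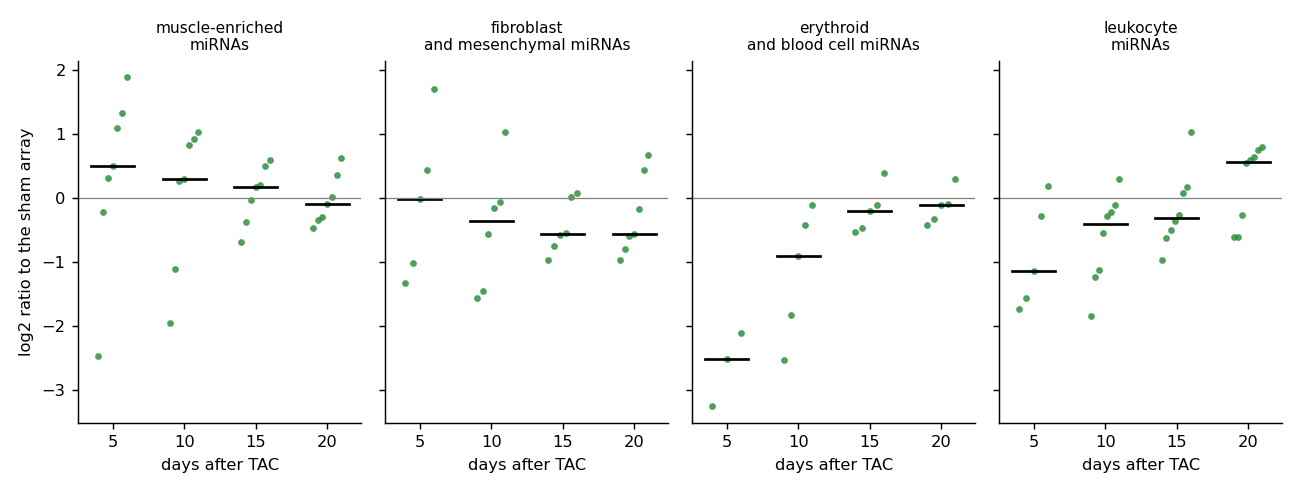
Log2 ratios to the sham array of the members of 4 lists fixed before the data were examined, by days after TAC, 1 point per miRNA above the floor on both arrays and black lines at the list medians. The erythroid medians were -2.52, -0.90, -0.21 and -0.12 and the leukocyte medians -1.15, -0.42, -0.32 and 0.57; with spike-in scaling these were all above 0 but the erythroid one on day 5 (-0.80), the fibroblast medians of days 5, 10 and 15 and the muscle-enriched median of day 20 changed sign, and median scaling turned the muscle-enriched median of day 5 to -0.33.

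Over the 16 lists and 4 arrays, 56 medians could be ranked against matched random lists and 4 lay in the lowest or highest 2.5 percent: the leukocyte and Dlk1-Dio3 lists above on day 20, the fibroblast list below on day 20 and the erythroid list below on day 10. By chance 2.8 would. The other ranked medians lay inside. The miR-17/92 list had a median of -0.48 on day 5 and between -0.29 and -0.27 afterwards, and with spike-in scaling it was above 0 on each array. The list named for the rodent repeat cluster of miR-297, miR-466 and miR-467, as fixed, also held members of the separate cluster of miR-290 to miR-295. Of its 4 measured members miR-294 and miR-291a-5p belong to that other cluster. The list had a median of 1.07 on day 5, with miR-294 at 1.21 and miR-466d at 0.93, and 0.06 on day 20, when quantile scaling over all probes turned it to -0.06. The miR-15/16 median was -0.62 on day 15 and -0.11 on day 20, and with spike-in scaling both were above 0. Both smooth muscle miRNAs read near sham by day 20 (miR-143 at 0.03 and miR-145 at -0.03), when the endothelial median was -0.06 (0.26 with spike-in scaling). Markers of other tissues were mostly below the floor, with 2 of 18 probes above it on both arrays on day 5 (miR-124, a neuronal miRNA, at 1.11 ± 0.53). With quantile scaling over all probes the day 5 values of miR-124 and miR-294 were 0.52 and 0.46.

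Across all 4 times, 86 of the 143 miRNAs above the floor on all arrays (60.1%) read on the same side of sham on every TAC array, 51 higher and 35 lower, where independent and equally varying arrays would give 40 percent. The count says that sham was often the highest or lowest array. The count in the same direction at all 4 times was 57 (39.9%) with plain background subtraction and 51 (35.7%) in blocks 19 to 36, no more than chance gives, and its split was 47 higher and 53 lower with median scaling and 104 and 3 with spike-in scaling. The TAC day 5 array was the highest or lowest for 111 of the 143 (77.6%). Higher at all 4 times were let-7c, miR-3571, miR-675, miR-450a*, miR-331*, miR-34b*, miR-323, miR-294, miR-183* and miR-340-5p, the 10 with the largest medians. Lower at all 4 times were miR-125b-5p, miR-130a, miR-125a-5p, miR-30e*, miR-499, miR-181a, miR-24-2*, miR-195, miR-146b and let-7b. The spots of each of these lower miRNAs overlapped those of sham on days 15 and 20, and those of miR-499 did at every time. On day 20 an alternative turned the sign of let-7c (-0.54), miR-34b* (-0.08) and miR-340-5p (-0.05). The same held there for miR-30e* (0.20), miR-499 (0.04), miR-195 (0.11) and miR-146b (0.24). MiR-331* alone differed 2-fold or more at all 4 times (3.72 ± 0.49, 1.29 ± 0.23, 1.10 ± 0.07 and 1.11 ± 0.09). That count of 1 ranged from 0 (floor 3 times higher) to 22 (spike-in scaling), and was 7 without the day 20 array and 2 without the day 10 array. In blocks 19 to 36 the log2 ratio of rno-miR-331*, TAC day 15, was 0.96.

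The planned test of the 4 TAC arrays as a group against the sham array, with limma, called 0 of 273 miRNAs at an adjusted p under 0.05, and 1 had an unadjusted p under 0.05. That miRNA, named after its value was seen, was miR-137* (adjusted p = 0.718 with limma). It was above the floor on sham alone, so no difference is given for it, and its sham spots had an SD of 1.88 and overlapped those of every TAC array. Under the alternatives with 3 or 4 TAC arrays limma also called 0, with 1 to 26 miRNAs at an unadjusted p under 0.05. The test has 3 residual degrees of freedom, takes the lone sham array to vary like the TAC arrays and counts change over time as spread. The TAC day 5 array was also set against the other 4 arrays, under the same assumption about the lone array. The test then called 51 miRNAs, 20 that read higher on day 5 and 31 that read lower. With the day 10, 15 or 20 array in that place it called 0.

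Within the TAC arrays, the farthest apart over time were miR-126, miR-143, let-7c, miR-451 and miR-125b-5p. MiR-126 read -3.80 ± 0.21 relative to sham on day 5, -1.06 ± 0.87 on day 10, -0.18 on day 15 and 0.06 on day 20. MiR-451 read -3.26 ± 0.06, -1.83 ± 0.98, -0.12 ± 0.49 and -0.12 ± 0.17. Let-7c went the other way, from 3.84 ± 0.52 to 0.43 ± 0.77. Of 144 miRNAs above the floor on all 4 TAC arrays, 90 (62.5%) spanned 2-fold or more, and the day 5 array was the highest or the lowest for 79 of the 90. The 4 arrays were ordered by day for 62 miRNAs (43.1%), 23 upward and 39 downward, where random order would give 8.3%. The order of the days is also the order of the spike-in signal. Without the day 5 array, 53 of 191 miRNAs spanned 2-fold or more.

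**Figure D3:**
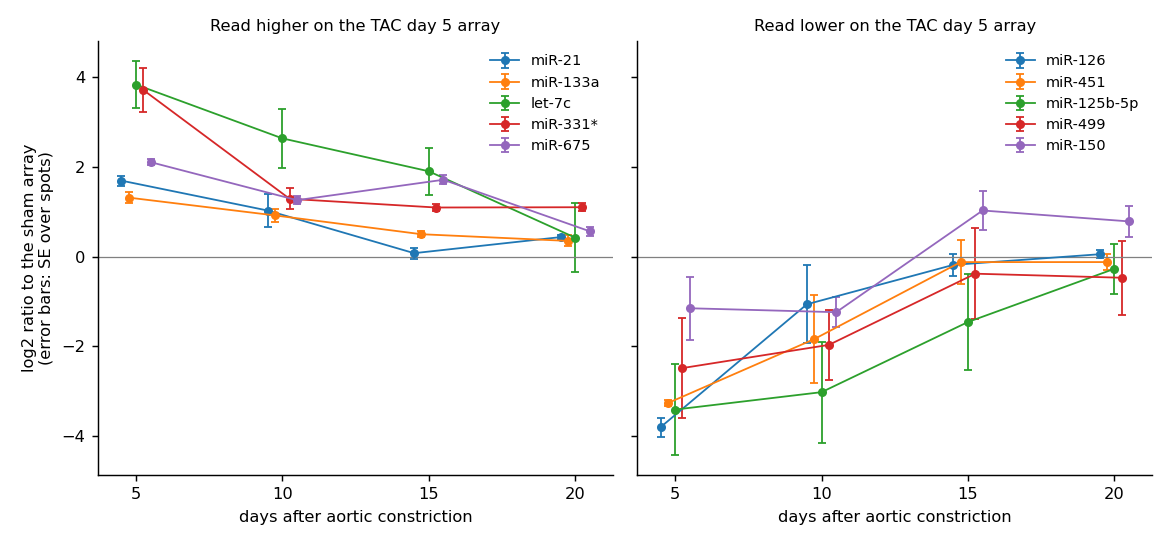
Log2 ratios to the sham array of 10 miRNAs by days after TAC, 1 array per day, with error bars of 1 SE over spots, which show technical spread only. MiR-21 goes from 1.70 on day 5 to 0.44 on day 20 and miR-126 from -3.80 to 0.06, while miR-331* stays at 1.10 or above at every time.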

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

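The spike-in, unnamed-probe, block-set, list-range, blood and leukocyte tests were chosen after the results were seen, while the limma count with each TAC array in the place of sham was planned. MiR-150, a lymphocyte miRNA, was singled out because it read above sham on 1 array and below it on another: 1.03 on TAC day 15 and -1.24 on day 10. MiR-193 was singled out in the same way, with 1.43 on day 20 and -1.68 on day 5. Neither difference was tested, since each time has 1 array. Probes without a name, which no comparison used, gave a signal above the floor on a TAC array and not on sham for 39 probes on day 5, 51 on day 10, 35 on day 15 and 107 on day 20, and what they detect is not known here.

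The large ratios on the TAC day 5 array come with lower spike-in signal and higher unnamed signal. Uneven hybridization between blocks 1 to 18 and blocks 19 to 36 is argued against on this array. Ratios from these block sets correlated at r = 0.884 across 152 miRNAs, which are not independent replicates. Unevenness shared by both block sets would not show in this value. Whether a lower hybridization yield accounts for miRNAs that read lower cannot be told from the spike-ins. Their median of -2.10 is relative to the miRNAs, so a loss common to all labelled RNA would not show in it. The median spike-in signal was 1955.8 units on sham and 151.8 on TAC day 5. That of miRNAs above the floor on all arrays was 1055.2 and 948.5 units. Signal from other sequences or background may account for miRNAs that read higher, since probes without a name had a median-scaled median of 1.10. On the same scale, reference probes below the floor on every array read from 0.99 (SNORD12) to 1.39 (SNORD49A). The value of 1.10 therefore cannot tell signal from other sequences apart from what the scale gives to dim probes. A response of the heart 5 days after constriction stays open as well. Limma called 51 miRNAs with this array against the other 4, but with 1 array in that arm the count decides neither, and the surgery cannot be told apart from the hybridization.

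The higher leukocyte miRNAs on the TAC day 20 array were present under every alternative run for that list, with medians of 0.40 or more, which argues against scaling or slide position as the whole cause. If more blood in that sample carried both, the erythroid median would be about as high as the leukocyte median. It was -0.12, or 0.19 with spike-in scaling. Its members were split, with miR-451 at -0.12 ± 0.17 and miR-144 at 0.29 ± 0.28. MiR-16 and miR-25 also stand in other lists, so the erythroid list cannot settle whether that sample held more blood. More leukocytes in the heart could be the source, as 5 of the 8 measured members read higher, but miR-181a, miR-181b and miR-146b read lower and 1 array gives no spread between hearts. Heart cells also express several members of the list, and with 56 list medians ranked, 2.8 would lie in the tails by chance. A difference in the hearts pooled or in days since surgery against the sham sample was not tested.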

How the results depend on the processing

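Quantile scaling over all probes, spike-in scaling, block sets, and days 15 and 20 only were chosen after results were seen; the rest were planned. Causes were not tested unless given. Counts at 2-fold on day 5 stayed between 71 and 152 (103 as reported). The others were 58 on day 10, 15 on day 15 and 4 on day 20, in that order below. Plain subtraction gave 91, 65 and 51, spike-in scaling 159, 70 and 33, blocks 1 to 18 98, 44 and 19, and the 1.5-fold threshold, by construction, 111, 55 and 39. The authors' values gave 34 on day 15 and 36 on day 20, and on day 20 median scaling gave 11, loess 7, quantile over all probes 8 and blocks 19 to 36 7. The 86 miRNAs in the same direction at all 4 times became 57 with plain subtraction, 51 in blocks 19 to 36 and, with more probes or fewer arrays, 328 with no filter, 159 of 201 with days 15 and 20 only, where chance gives 66.7%, and 91 to 118 leaving out 1 TAC array. The 90 spanning 2-fold became 152 with no filter, 11 with days 15 and 20 only and 53 (without day 5) to 90 leaving out 1. Limma calls stayed at 0 leaving out 1 array (0 to 0) and elsewhere, with smallest adjusted p from 0.167 to 0.861, but were 14 with days 15 and 20 only, where 1 residual degree of freedom is left. The 4 list medians in the tails became 9 with no filter and 9 in blocks 1 to 18. Among named ratios at 2-fold and list medians in the tails, signs reversed for the erythroid median on day 10 (spike-in scaling, 0.59), for day 5 miR-29b (median scaling, -0.12), miR-1 (median scaling, -0.19, and quantile over all probes, -0.13) and miR-29a (blocks 19 to 36, 0.63), and for day 10 miR-126 (0.11) and miR-195 (0.067), both in blocks 19 to 36. Of 56 ranked list medians, in the tails or not, 34 changed sign with spike-in scaling (by construction, through a shift common to all miRNAs), 13 with plain subtraction, 9 in blocks 19 to 36, 8 with quantile over all probes, 6 with median scaling and 6 in blocks 1 to 18. Of 47 named ratios at 2-fold on day 5, 36 or more stayed there under each alternative run for named miRNAs (not spike-in scaling) that kept the floor. So did 28 or more of 40 on day 10, 7 or more of 14 on day 15 and 3 or more of 4 on day 20. Signal over background limits what can be detected: the floor was 72.1 units on day 5 and 30.6 on sham.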

Other observations

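All tests in this part were chosen after the results were seen. With sham and the TAC day 15 and 20 arrays alone, limma called 14 of 273 miRNAs, 9 higher and 5 lower in TAC, named here after their values were seen. Those above the floor on all 3 arrays were miR-450a* (1.29), miR-3571 (1.20), let-7c-1* (1.19), let-7c (1.17), miR-675 (1.14) and miR-331* (1.10), which were higher, and miR-125a-5p (-1.16), which was lower. The other 7 calls rest on signal below the floor on at least 1 of the 3 arrays, so no difference is given for them. MiR-31, a mesenchymal miRNA, read -0.97 on day 20 and was at least 1.86-fold lower on day 15, and miR-136 was at least 1.47-fold lower on day 15. MiR-31* and miR-137* were above the floor on sham alone, and the 4 sham spots of miR-137*, the call with the smallest adjusted p, had an SD of 1.88 and overlapped those of each TAC array. MiR-203, miR-196b* and miR-221* were above the floor on TAC arrays alone. The test has 1 residual degree of freedom, borrows its spread from other miRNAs, and called 3 with the TAC day 15 array in the place of sham and 0 with day 20. Over the settings with 3 or 4 TAC arrays the smallest adjusted p ranged from 0.167 to 0.861.

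Star strands, the strand of a miRNA duplex that is usually degraded, read higher more often than other miRNAs on day 5, with 23 of 44 (52.3%) at 2-fold or more against 40 of 108 (37.0%), a difference that was not tested. On day 20 these were 2 of 65 and 1 of 166. Among 15 pairs with both strands measured on day 5, the star read 2-fold or more higher in 3. In 2 of those 3 the other strand did too, so these pairs do not set the star strand apart. Small nuclear and nucleolar RNAs, often used as references, also diverged on day 5, within both classes. RNU5 read 1.42, RNU1 1.20 and RNU6-1 1.52, but the probe for RNU6-1 and RNU6-2 together read -1.11. SNORD65 read -3.33, SNORD13 -2.43, SNORD38B -1.15 and SNORD2 -0.93, but SNORD3@ read 1.05 and SNORD6 0.92. These ratios are median-scaled. On that scale, reference probes below the floor on every array also read from 0.99 (SNORD12) to 1.39 (SNORD49A) on day 5. Ratios near 1, such as those of SNORD3@ and SNORD6, therefore do not show by themselves that an RNA rose. SNORD65 had 12586 units of signal on sham and 873 on day 5.

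A hypothesis was that miRNA genes within 10 kb of each other, often transcribed together, read more alike than other pairs. On day 5 the mean absolute difference in log2 ratio was 1.28 over 31 neighbouring pairs and 1.84 with values shuffled (permutation test, one-sided p = 0.0152, adjusted 0.0376 over 4 arrays). On day 10 it was 0.79 over 37 pairs against 1.07 (permutation p = 0.0188, adjusted 0.0376), and on days 15 and 20 the adjusted permutation p was 0.0642. Similar brightness of neighbours is argued against, as the adjusted permutation p was 0.0251 on day 5 with shuffling within brightness classes. Sequence shared within families could account for day 10, where the permutation p was 0.181 without pairs of a family; on day 5 the difference without them stayed at 1.25 over 28 pairs against 1.84 shuffled (permutation p = 0.0162, adjusted 0.0648), so removing them did not lessen the gap, and with 3 pairs removed and the adjusted p past 0.05 the day 5 values settle nothing further.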
